A study of Mus musculus with 6 samples.

How the data were processed

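Chromatin immunoprecipitation on microarrays was deposited for H3K4me3, H3K27me3 and Ring1B in mouse chromatin labelled thymocytes, 6 arrays in all. Per the labels, each array compared immunoprecipitated DNA (Cy5) with input DNA (Cy3), both amplified by linker-mediated PCR. The titles number the arrays of an antibody 1 and 2. These are different designs with 0 probes in common, 9 chromosomes on array 1 and 15 on array 2, with chromosome 9 and, by 1 probe on array 2, chromosome 8 on both, so they were treated as parts of 1 sample and not as replicates. PCR-amplified DNA and the number of arrays limit the precision.

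Per the file headers, the deposited intensity values come from Agilent Feature Extraction 10.1.1.1. It subtracted the background, removed spatial and multiplicative trends, scaled each channel by a linear dye normalisation, and set surrogate values for spots not above background. Raw mean signals and local background intensity were also used as deposited. The log10 ratio of the deposited scanner files is Cy5 over Cy3, per the file headers, and the p-value of each spot's ratio comes from the scanner software's error model, per the file headers. The deposited value table holds a natural log ratio that equals input over ChIP of the processed signals, the opposite direction, without centring. After turning the sign, its largest difference from the scanner ratios was 7.21e-07 on the log2 scale. The medians of its columns were 0.33, 0.03 and 0.04 for H3K4me3, H3K27me3 and Ring1B on array 1 and 0.45, 0.02 and 0.07 on array 2. The genome build of the probe positions is not given in the sources used here.

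The ratio of each probe was log2 of processed Cy5 over processed Cy3 signal. Control spots and non-uniform outliers (7 to 20 probes per array) were left out, and the array median was subtracted, with no loess or quantile step. Probes were assigned to genes by the deposited annotation column. Symbols were updated through RefSeq accessions with a table of the GRCm38 assembly, from which no coordinate was taken. Of 16908 symbols 16294 matched and 3414 were renamed. Of 474380 probes 462748 were assigned to a gene and 10894 had no RefSeq gene. Neighbouring probes started 182 bases apart (median).

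The value of a gene was the highest mean of 3 neighbouring probes within 1500 bases. Genes needed at least 5 usable probes. A gene was called at the lowest threshold, from 1.5-fold upward in steps of 0.05 log2, at which genes with a window below the mirrored threshold numbered at most 5% of the calls. Overlaps were compared with the number that independent lists would share. The value rule, the thresholds, the 16 preset gene lists and the processing alternatives were fixed before the data were examined. Values within 1000 bases of the start site, and the added H3K27me3 threshold, were chosen after seeing the data.

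Preset lists covered T cell identity, B cell, myeloid, erythroid and megakaryocyte, and peripheral effector T cell genes, cyclin-dependent kinase inhibitors, Polycomb proteins, housekeeping and ribosomal protein genes, Hox genes, developmental transcription factors, signalling ligands, olfactory receptors, liver secreted proteins, thymic stroma and the cell cycle. The 7 lists added after the data were seen covered epithelial, lymphoid, thymic epithelial, epidermal, fibroblast, endothelial and neuronal genes. The members of the added epithelial and lymphoid lists were written down before their own values were seen. Each list's median was set against 10000 random lists of that size, matched on array and on probe number.

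Genes named in the text are, by a preset rule, the 8 highest per antibody and per class of marks, the 4 highest and 2 lowest for Ring1B in each preset list, and a fixed set of T cell, Polycomb and control genes, of which 3 were not measured. The rule was applied to the classes of the added threshold too. Cd3d, Cd3g, Dntt, Lck, Thy1, Rag2, Krt5, Krt8, Krt14, Epcam, Foxn1, Cbx7, Cbx8, Ezh2, Fgf9, Six2, Ocln, Has2, Dbr1, Armc8, Pax1, Pax9, Eya1, Tbx1, Itgb4, Klf5, Dsc3, Ptcra, Ccr9 and Cd3eap were chosen after their values were seen.

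The calling procedure was tested on simulated data with the noise of the noisiest array (SD 0.66 log2, against 0.42 on the least noisy) over 16583 genes. With enriched genes only, it called 24 of 50 genes planted at 1.5 log2, 48 of 50 at 2.5 and all 50 at 3.5 and at 4.5, with 10 false calls among 190. The rest of the calls were genes that share planted probes. With 8000 depleted genes added, each shifted by -2 log2 over 5 probes, the threshold rose from 1.88 to 4.78. It then called 0 of 50 at 3.5 and 22 of 50 at 4.5. These counts do not give the sensitivity of the H3K27me3 arrays. There the preset threshold was 3.08, and genes with an H3K4me3 call had a median lowest window of -1.38.

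Alternatives were normexp background correction (offset 50), the uncentred log ratio, centring on the mode, the median of all probes, windows of 5 probes, bright probes, thresholds of 2-fold, a mirrored share of 1% and the top 10%, each array alone, the deposited value table, at least 10 probes, and a probe p-value under 0.01. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.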

Results

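Chromatin labelled thymocytes, from the thymus of C57BL/6J mice, was immunoprecipitated with 3 antibodies and hybridised to promoter arrays. Thymocytes are the developing T cells that make up most of the thymus. One antibody recognised Ring1B, the catalytic ubiquitin ligase of Polycomb repressive complex 1, which the gene Rnf2 encodes. The others recognised H3K27me3, the histone mark laid down by Polycomb repressive complex 2, and H3K4me3, a mark of active or poised promoters. Each antibody was read on a pair of array designs that share 0 probes and split the promoters by chromosome, so each antibody had 1 sample and no replicate. The set carried 474380 probes, and 16583 genes had enough usable probes to be measured, with a median of 28 probes per gene over all genes of the set. Input spots had a median raw signal of 41.4 to 52.7 on the 6 arrays against a local background of 14 to 16.5. ChIP spots had a median of 70.0 to 95 against 39 to 41. Spots well above background made up 75.0% to 89.1% of the input channel and 81.7% to 95.7% of the ChIP channel. Control spots printed repeatedly (480 per array) varied by 0.0992 to 0.129 on the log2 scale (SD).

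Every value below is a log2 ratio of ChIP over input relative to the array median, as the highest mean of 3 neighbouring probes of a promoter. The deposited value table runs in the opposite direction, input over ChIP. The error given with a gene is the SD over the 3 probes of its window, which measures neither biological nor hybridisation error. With 1 sample per antibody no difference has a replicate check, and no p-value across genes was computed. Intervals of shares are exact 95% Clopper-Pearson intervals and cover counting error only. They and the expected overlaps count genes as independent. Neighbouring genes can share probes, so the intervals can be too narrow. Each array carried 1 antibody, so array and antibody cannot be told apart. Probe ratios of H3K4me3 and H3K27me3 were negatively correlated, with a Pearson r of -0.30 on array 1 and -0.35 on array 2. The dyes are stated in the labels and these marks can oppose each other, so the direction was kept.

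The H3K4me3 arrays address which promoters carried the mark. Signal was highest at genes that most cells use. The 8 highest named genes included the RNA helicase gene Ddx42 at 6.97 (SD 0.60), the ribosomal protein gene Rps14 at 6.96 (SD 1.15) and Mcl1, which encodes a survival factor of the Bcl2 family, at 6.93 (SD 0.37). All 36 measured housekeeping genes were called, among them Actb, cytoplasmic actin, at 5.69 (SD 0.21) and Gapdh, a glycolytic enzyme, at 6.33 (SD 0.98). Of 81 ribosomal protein genes 79 were called, and of 31 cell cycle genes 31. None of 939 olfactory and vomeronasal receptor genes, which are used in sensory neurons, was called, which allows a share of up to 0.392% by the exact interval, and their median was -0.51.

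In all, 10158 of 16583 genes (61.3%, interval 60.5% to 62.0%) passed the H3K4me3 threshold of 2.28, which is 4.87-fold. The count was 5061 of 8375 genes on array 1 and 5097 of 8208 on array 2. Windows below the mirrored threshold occurred at 425 genes. The windows lay close to the start site, at a median distance of 441 bases downstream (quartiles 196 and 695), and 84.3% lay within 1000 bases. Using the median of all probes of a promoter, in place of the highest window, left 3462 genes called.

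The H3K27me3 arrays address which promoters carried the mark of Polycomb repressive complex 2. The highest values lay at Adcyap1, which encodes the neuropeptide PACAP, at 3.39 (SD 0.33), at the homeobox genes Nkx2-3 and Nkx2-2 at 3.12 (SD 0.12) and 3.10 (SD 0.11), and at Gpr26, an orphan receptor gene expressed in brain, at 3.09 (SD 0.38). These 4 genes were the only ones past the preset threshold of 3.08 (8.49-fold), a share of 0.0241% (interval 0.00657% to 0.0617%). The Adcyap1 window lay on chromosome 17 from 93505646 to 93506020, 2116 bases downstream of the start site. The highest H3K27me3 value, 3.39, lay below those of H3K4me3 (7.02) and Ring1B (7.77). The gene medians were 0.50, 3.98 and 0.61 in that order.

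The preset threshold counts windows of low signal as a measure of error, and H3K27me3 was low at promoters with H3K4me3. A window at or below -1 occurred at 7806 of the 10158 genes with an H3K4me3 call (76.8%) and at 1134 of the 6425 others (17.6%). A lower threshold was therefore added after the data were seen, in which low windows counted only at genes without an H3K4me3 call. It came to 2.03 (4.10-fold) and called 1146 genes (6.91%, interval 6.53% to 7.31%), 576 on array 1 and 570 on array 2. Mirrored low windows occurred at 551 genes, 43 of them without an H3K4me3 call, so H3K27me3 calls at genes with H3K4me3, 173 in all, are outnumbered by such windows there. H3K27me3 calls below use this lower threshold unless the preset one is named. These windows were spread along the promoter, and 28.4% lay within 1000 bases of the start site. Thresholds of 2-fold called 5267 genes and normexp background correction called 5300.

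Ring1B was highest at genes of transcription factors that direct the formation of other tissues. The highest were Gata4, a heart and gut endoderm factor, at 7.77 (SD 0.56), Sim1, a hypothalamic factor, at 7.67 (SD 0.88), Tbx20, a cardiac factor, at 7.51 (SD 1.099), and Dmrt3, a spinal interneuron factor, at 7.48 (SD 0.25). Eomes, a T-box factor of the early embryo and of killer lymphocytes, followed at 7.21 (SD 0.46), then the neuronal factor gene Tlx3 at 7.17 (SD 0.58). The Gata4 window lay on chromosome 14 from 62202396 to 62202804, and its offset from the start site was -3226 bases, upstream of the gene. The genome build of these positions is not given in the sources used here.

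Of 16583 genes, 1323 passed the Ring1B threshold of 2.38 (5.22-fold), a share of 7.98% (interval 7.57% to 8.40%), 640 on array 1 and 683 on array 2. Mirrored low windows occurred at 61 genes. Ring1B windows lay farther from the start site than those of H3K4me3, with 44.0% within 1000 bases and quartiles at -1102 and 1169 bases. At a threshold of 2-fold 4347 genes were called, normexp background correction gave 5276, and the median of all probes gave 745.

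**Figure D1:**
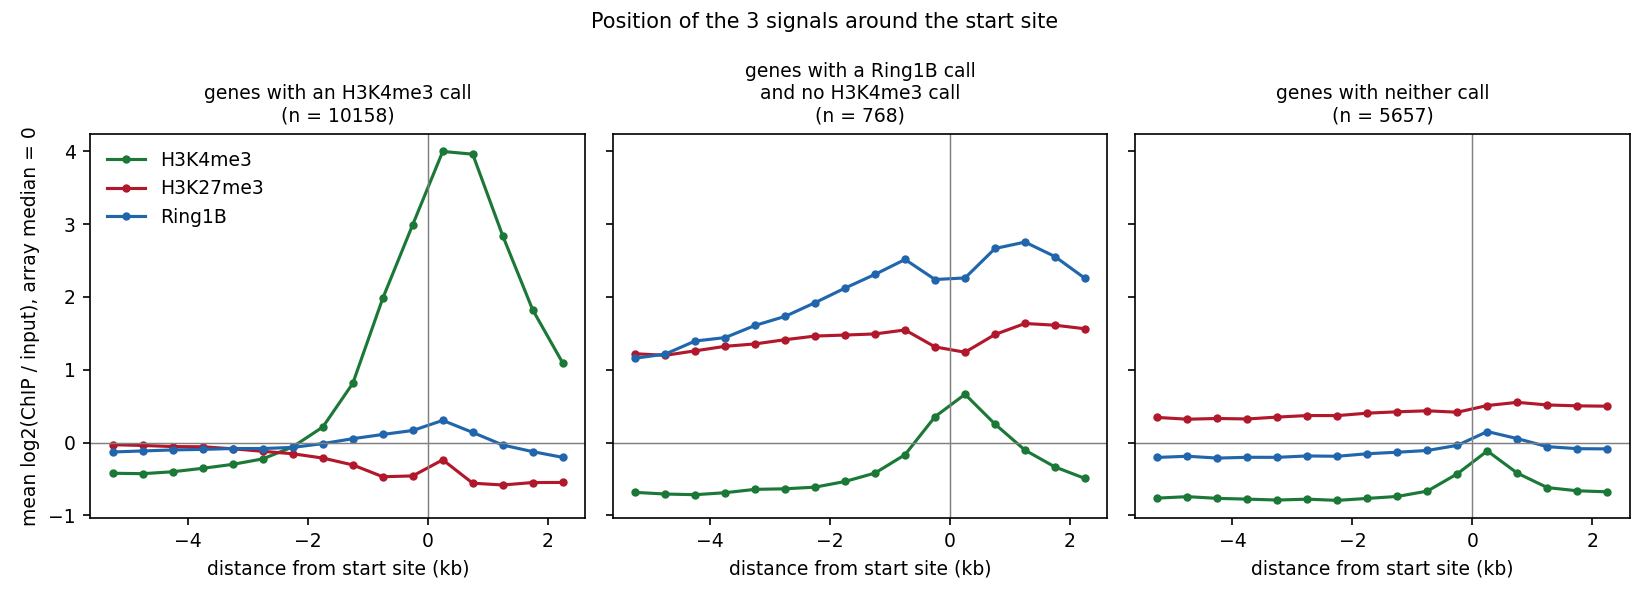
Mean probe log2 ratio of ChIP over input in bins of 500 bases against distance from the start site in kb, for the 10158 genes with an H3K4me3 call, the 768 with a Ring1B call and no H3K4me3 call, and the 5657 with neither. Each line is 1 antibody; in the left panel H3K4me3 peaks just downstream of the start site and H3K27me3 falls to -0.58 from 1000 to 1500 bases downstream, and in the middle panel Ring1B and H3K27me3 are raised across the whole promoter.

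Many promoters with Ring1B also carried H3K27me3. Of the 1323 genes with a Ring1B call, 668 (50.5%, interval 47.8% to 53.2%) also had an H3K27me3 call, where 91.4 would be shared by independent lists, a ratio of 7.31. All 8 genes with the highest Ring1B were among them, Gata4 with an H3K27me3 value of 2.67 and Sim1 with 2.81. In the other direction, 58.3% of the genes with an H3K27me3 call had Ring1B. Under the preset H3K27me3 threshold 3 genes were shared, Adcyap1, Nkx2-3 and Nkx2-2, where independent lists would share 0.319 genes, a ratio of 9.40. These 3 are 0.227% of the Ring1B genes, and only 4 genes passed that threshold. Without any H3K27me3 threshold, the median H3K27me3 of Ring1B genes was 2.04 (interval 2.00 to 2.07) and that of the other 15260 genes 0.42 (interval 0.41 to 0.44). A value above 2-fold occurred at 93.0% of the Ring1B genes and at 26.4% of the others.

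The share with Ring1B rose along the H3K27me3 scale. Genes were split by H3K27me3 into 10 bins of equal size. In the lowest bin 0 of 1659 had Ring1B, which allows a share of up to 0.222% by the exact interval. In bin 9 the share was 16.7% and in bin 10, the highest, 48.9%, or 812 of 1659. Across genes, which are not independent replicates, Spearman's rho of Ring1B and H3K27me3 was 0.58, with 0.60 on array 1 and 0.58 on array 2. Some promoters with high H3K27me3 had no Ring1B call. Besides Gpr26, with a Ring1B value of 1.35 (SD 0.06), these included Otof, the hair cell gene for otoferlin, at 1.21 (SD 0.54), Lrg1, a secreted glycoprotein gene, at 1.44 (SD 0.33), and Smoc1, a matricellular protein gene, at 2.28 (SD 0.38), just under the threshold. Otof shared its H3K27me3 window with the neighbouring gene Fam166c.

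**Figure D2:**
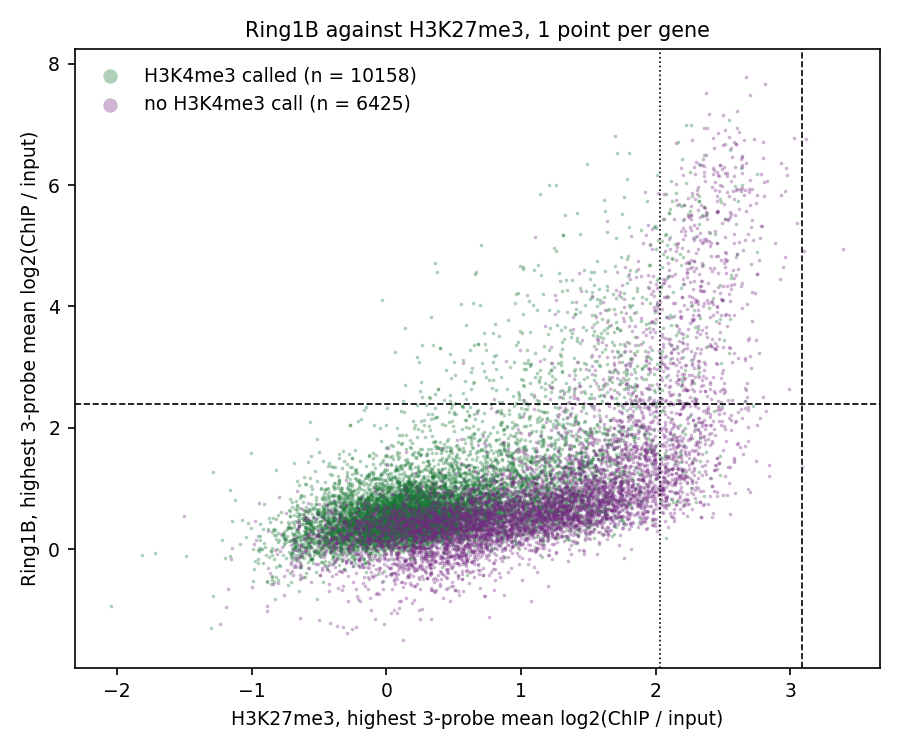
Highest 3-probe mean log2 ratio of ChIP over input for Ring1B (vertical) against H3K27me3 (horizontal), 1 point per gene, coloured by H3K4me3 call (10158 with, 6425 without). The horizontal dashed line marks the Ring1B threshold of 2.38 and the vertical lines mark the preset (dashed, 3.08) and the added (dotted, 2.03) H3K27me3 thresholds.

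At the preset thresholds, Ring1B and H3K4me3 were shared at fewer promoters than independent lists would give. Of the Ring1B genes 555 (42.0%, interval 39.3% to 44.7%) had an H3K4me3 call, against 61.3% of all genes and 810 for independent lists, a ratio of 0.685. This direction turned under thresholds of 2-fold, where 74.0% of Ring1B genes and 69.6% of all genes had H3K4me3, and under normexp background correction, where the shares were 77.6% and 69.2%. Centring on the mode gave 68.8% and 67.7%. With the Ring1B calls kept, H3K4me3 above 2-fold occurred at 76.0% of the Ring1B genes and at 69.0% of the others. The median H3K4me3 went the other way, at 1.82 and 4.19. The relation along the H3K4me3 scale was not monotonic. Of 10 equal bins by H3K4me3, Ring1B was called at 0.964% of genes in the lowest, at 32.0% in bin 4, whose median H3K4me3 was 1.63, and at 1.21% in the highest. Spearman's rho across genes was 0.01 for Ring1B and H3K4me3 and -0.41 for H3K27me3 and H3K4me3. At the 8291 genes with H3K27me3 below its median, rho of Ring1B and H3K4me3 was 0.27. At the Ring1B window itself, the median H3K4me3 of Ring1B genes was 0.25 and the median H3K27me3 1.72.

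Promoters were then sorted by both marks. Ring1B was most frequent where both marks were called, at 124 of 173 genes (71.7%, interval 64.3% to 78.3%). Among these were the endoderm factor gene Gata6, the protocadherin gene Pcdh10, the limb factor gene Sp8 and Igf2bp1, a fetal RNA-binding protein gene, with Ring1B values of 7.08 (SD 0.34), 7.00 (SD 0.23), 6.58 (SD 0.56) and 6.43 (SD 0.74). The marks of a gene need not lie at the same place, and the Igf2bp1 window of Ring1B lay at -5309 bases and that of H3K4me3 at 648 bases. Genes with H3K27me3 alone had Ring1B at 544 of 973 (55.9%, interval 52.7% to 59.1%), and these included Gata4, Sim1 and Tbx20. These 544 genes lacked an H3K4me3 call but were not free of H3K4me3, with a median of 1.13. At the 768 genes with Ring1B and no H3K4me3 call, mean H3K4me3 from 0 to 500 bases downstream was 0.66. Genes with neither call had -0.11. At thresholds of 2-fold, 1997 Ring1B genes had both marks and 1059 had H3K27me3 alone. The shares for both marks and for H3K27me3 alone lay far above those of the remaining classes. Their order turned when the top 10% of genes were called for each antibody, at 3 of 7 genes (42.9%) with both marks and 56.8% of those with H3K27me3 alone.

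Genes with H3K4me3 alone had Ring1B at 431 of 9985 (4.32%, interval 3.93% to 4.73%). They included the odd-skipped factor gene Osr2 at 6.80 (SD 0.62), the forebrain factor gene Emx2 at 6.52 (SD 0.23), the motor neuron factor gene Isl2 at 6.52 (SD 1.04) and Ebf3, an early B cell factor family gene, at 6.16 (SD 0.44). The H3K27me3 value of Ebf3, 2.01, was just under the threshold, and Osr2, Emx2 and Isl2 stood at 1.70, 1.71 and 1.80. These 431 genes were mostly not free of H3K27me3, with a median of 1.47. The 9554 genes with H3K4me3 alone and no Ring1B had 0.25. Genes with neither mark had Ring1B at 224 of 5452 (4.11%, interval 3.60% to 4.67%), led by Mafa, a beta cell factor gene, at 5.88 (SD 1.40) and Gad2, the gene of a GABA-synthesising enzyme, at 5.87 (SD 0.58). These 224 genes were not free of H3K27me3, with a median of 1.79, and Mafa at 1.92 and Gad2 at 2.02 lay just under the threshold. Under the preset threshold no gene had both marks, and the shares were 3 of 4 for H3K27me3 alone, 555 of 10158 (5.46%) for H3K4me3 alone and 765 of 6421 (11.9%) for neither. The order of these last classes depended on the threshold, and at 2-fold the shares were 14.1% for H3K4me3 alone and 2.69% for neither.

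**Figure D3:**
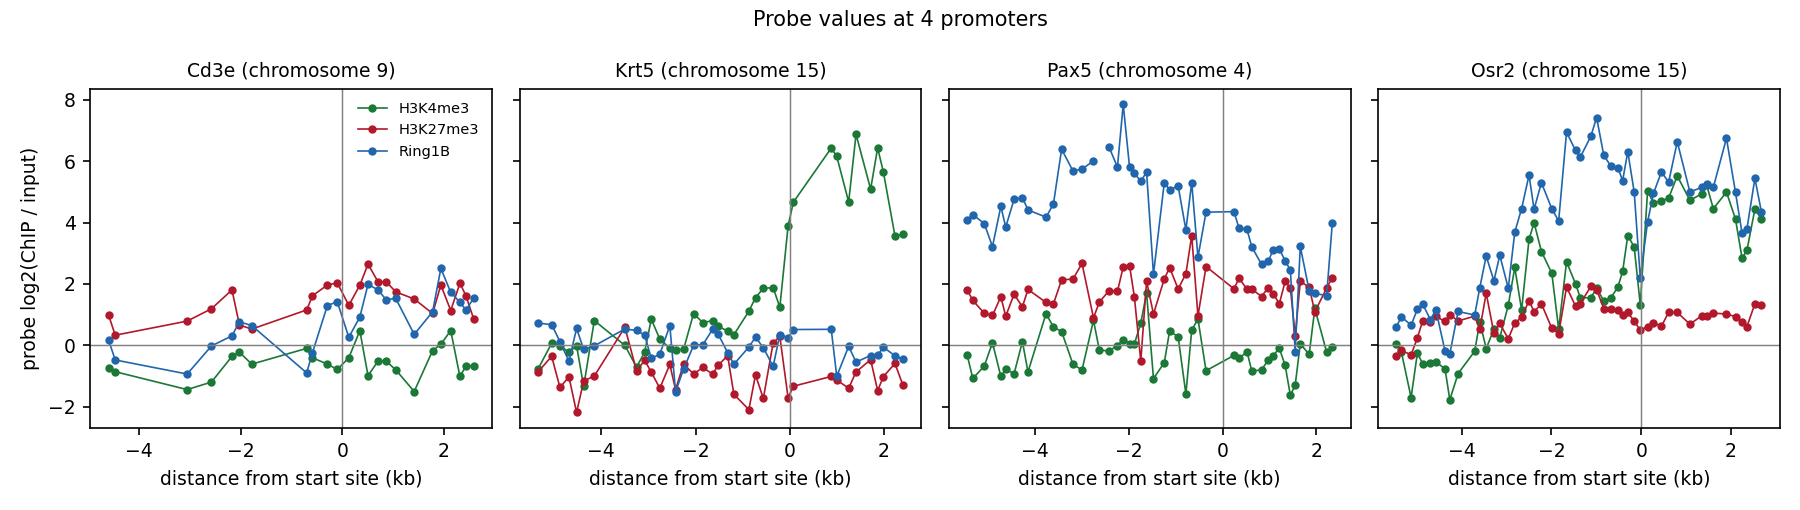
Probe log2 ratios of ChIP over input against distance from the start site in kb, within 6 kb, at Cd3e (24 probes), Krt5 (37), Pax5 (47) and Osr2 (50), 1 line per antibody. Promoter values of H3K4me3, H3K27me3 and Ring1B were 0.12, 2.26 and 1.88 at Cd3e, 6.13, -0.24 and 0.51 at Krt5, 0.83, 2.58 and 6.71 at Pax5, and 5.06, 1.70 and 6.80 at Osr2.

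T cell identity genes split into a group with H3K4me3 and a group without. Of 42 measured, 19 had H3K4me3 (45.2%, interval 29.8% to 61.3%), 10 had H3K27me3 and 10 had Ring1B. The upper limit of this H3K4me3 interval reaches the 61.3% of all genes. Genes with H3K4me3 included Bcl11b, a factor of T lineage commitment, at 5.15 (SD 0.38), Zbtb7b, the factor of the CD4 lineage, at 6.20 (SD 0.46), the surface antigen gene Thy1 at 5.34 (SD 0.66) and the kinase gene Lck at 4.74 (SD 0.46). The CD3 chain genes of the T cell receptor complex named here did not. Cd3d, Cd3e and Cd3g had H3K4me3 values of -0.14 (SD 0.36), 0.12 (SD 0.33) and -0.15 (SD 0.88), and H3K27me3 values of 2.12, 2.26 and 2.16. The co-receptor gene Cd4 stood at 0.50 (SD 0.32) for H3K4me3 and 2.17 for H3K27me3, and Dntt, the terminal transferase of receptor gene assembly, at -0.03 (SD 0.71) and 1.97.

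The H3K4me3 median of the T cell list was 1.80 (interval 0.50 to 3.64), at percentile 2.28 among 10000 random lists of that size matched on array and probe number. Its H3K27me3 median of 1.22 lay at percentile 99.4, and its Ring1B median of 1.00 at percentile 98.6. A high H3K27me3 percentile was not particular to this list. The B cell, myeloid, erythroid, peripheral T cell, liver and olfactory lists lay at percentiles 98.9 to 100. Random lists were not matched on H3K4me3, and H3K27me3 was low at promoters with it. A high percentile alone therefore does not show enrichment. H3K27me3 was called at 1.06% of olfactory and 6.67% of myeloid genes, against 6.91% of all genes. It was called at 13.6% to 14.3% of the B cell, erythroid, peripheral T cell and liver genes. Epithelial markers of an added list carried H3K4me3 more often in the same chromatin, though epidermal differentiation genes, given below, did not. On this list of 39 genes, added after the data were seen, 36 had H3K4me3 (92.3%, interval 79.1% to 98.4%), with a median of 5.60, and on an added lymphoid list of 36 genes 9 had it (25%, interval 12.1% to 42.2%), with a median of 0.62. The lymphoid list includes Cd3eap, an RNA polymerase I subunit gene, by its name. Neither list shared a gene with any other. Over the processing alternatives the H3K4me3 counts ran from 2 to 23 of 42 T cell, from 12 to 37 of 39 epithelial and from 3 to 14 of 36 lymphoid genes. The H3K4me3 window of Rag2, a recombinase gene with a value of 4.28, lay 4009 bases downstream of its start site.

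Among T cell genes with Ring1B, Lef1, a Wnt pathway factor, had 6.28 (SD 0.61), the zinc finger factor genes Gfi1 and Ikzf1 had 5.89 (SD 0.61) and 5.82 (SD 0.43), and Runx1, a factor of blood stem cells and T cells, had 5.44 (SD 0.40). Ccr9, a chemokine receptor gene, had 4.65 (SD 0.48). Gata3, required throughout T cell development, had Ring1B at 3.60 (SD 0.73) with H3K4me3 at 5.54 (SD 0.24). Of the 10 genes with Ring1B, 6 also had H3K4me3 and 6 had H3K27me3. Cd3e stayed below the threshold at 1.88 (SD 0.57), and Cd4 at 1.19 (SD 0.49). Lef1, Gfi1, Ikzf1 and Runx1 had H3K27me3 values of 2.43, 2.53, 2.33 and 2.05. Their H3K4me3 values were 1.66, 0.46, 2.40 and 6.10, and Lef1 and Gfi1 had no H3K4me3 call. Cd8a, Rag1 and Runx3 were not measured.

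Single factors of the B cell, erythroid and myeloid lists carried Ring1B. The shares of these lists with Ring1B had intervals that include the 7.98% of all genes. Whether the chromatin came mainly from T cells is weighed at the end. The B cell commitment factor gene Pax5 had 6.71 (SD 1.04) with H3K27me3 at 2.58, and Ebf1, another B cell factor gene, had 4.31 (SD 0.42) with H3K4me3 at 4.47. In the B cell list 4 of 28 genes had Ring1B and 6 had H3K4me3. In the erythroid and megakaryocyte list 3 of 22 had Ring1B, namely the stem cell factor genes Tal1 at 6.06 (SD 1.07), Lmo2 at 4.69 (SD 1.62) and Gata2 at 3.87 (SD 0.13), while the erythroid factor gene Gata1 stood at 0.40 (SD 0.26). In the myeloid list 1 of 30 had Ring1B, the lipopolysaccharide co-receptor gene Cd14 at 4.97 (SD 1.25), and Cebpa, a granulocyte factor gene, stood at 1.68 (SD 0.33). H3K4me3 was called at 6 of the myeloid and 4 of the erythroid genes. The Ring1B medians of the B cell, erythroid and myeloid lists lay at percentiles 87.4, 57.0 and 97.9 of random lists.

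Of 35 genes of peripheral effector and regulatory T cells 5 had Ring1B and 7 had H3K4me3. The interval of this Ring1B share, 4.81% to 30.3%, includes the 7.98% of all genes, and the Ring1B median lay at percentile 81.1 of random lists. Genes with Ring1B included Eomes, the homeobox gene Hlx at 6.21 (SD 0.09), and Zbtb16, the factor of innate-like T cells, at 3.38 (SD 0.44). Tbx21, the T helper 1 factor gene, reached 2.38 (SD 0.15) and was not called. Foxp3, the regulatory T cell factor gene, stood at 1.69 (SD 0.92). Its H3K4me3 value of 3.85 came from a window at an offset of -5116 bases, and the value within 1000 bases of the start site was -0.59.

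Genes of Polycomb proteins themselves were among the Ring1B targets. Of 27 measured, 7 had Ring1B (25.9%, interval 11.1% to 46.3%) and 26 had H3K4me3. Those with Ring1B included Cbx2 at 5.73 (SD 0.14), Pcgf1 at 5.54 (SD 0.71), Bmi1 at 4.03 (SD 0.49), Cbx8 at 3.36 (SD 0.40), Cbx7 at 2.65 (SD 0.67) and Ezh2 at 2.59 (SD 0.16). All 7 also had H3K4me3, and Pcgf1 alone passed the H3K27me3 threshold, at 2.10. The Pcgf1 windows of Ring1B and H3K27me3 lay at offsets of -7432 and -6141 bases, away from its H3K4me3 window at -82 bases. Rnf2, the gene of Ring1B, stood at 1.43 (SD 0.52), and its paralogue Ring1 at 0.77 (SD 0.81). The list median of Ring1B was at percentile 98.5 of random lists.

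None of 6 measured cyclin-dependent kinase inhibitor genes was called for Ring1B or H3K27me3, which allows a share of up to 45.9% by the exact interval. Cdkn2a, a classic Polycomb target that encodes p16 and p19Arf, had H3K4me3 at 5.08 (SD 0.67), H3K27me3 at 0.19 (SD 0.07) and Ring1B at 0.77 (SD 0.10). Cdkn1c, which encodes p57, had 1.33 (SD 0.49), 1.49 (SD 0.12) and 1.04 (SD 0.40). Of these 6 genes, 5 had H3K4me3. In the cell cycle list 1 of 31 genes had Ring1B, the cyclin gene Ccnd2 at 5.86 (SD 0.38), in a window at -4857 bases, with H3K4me3 of 6.21 in a window at 541 bases. None of the 36 housekeeping genes had Ring1B, which allows a share of up to 9.74% by the exact interval. Among ribosomal protein genes Rpl30 had it, at 2.43 (SD 0.25), in a window at an offset of -7943 bases.

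Ring1B covered the Hox clusters. Of 33 measured Hox genes 32 had Ring1B (97.0%, interval 84.2% to 99.9%) and 27 had H3K27me3, with medians of 5.35 and 2.50. Genes of a cluster are neighbours and not independent, which neither this interval nor the random lists take into account. Hoxd13, a factor of digits, had Ring1B at 6.18 (SD 0.80), Hoxa9, a factor of blood progenitors, at 5.79 (SD 0.46), and Hoxc10, a posterior factor, at 6.45 (SD 0.20). Developmental transcription factors followed, with Ring1B at 142 of 183 (77.6%, interval 70.9% to 83.4%), H3K27me3 at 121 and H3K4me3 at 62. Among Wnt, BMP, FGF and hedgehog ligands 31 of 65 had Ring1B (47.7%) and 24 had H3K27me3, led by Wnt1, a midbrain and neural crest signal, at 6.16 (SD 0.20). The Ring1B medians of these lists, 4.92 and 2.23, and that of the Hox list each lay at percentile 100 of random lists.

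Olfactory receptor genes lacked Ring1B calls. Of 939 olfactory and vomeronasal receptor genes 0 had Ring1B and 10 had H3K27me3, and the Ring1B median was 0.17. The share with H3K27me3, 1.06%, lay below the 6.91% of all genes. Their H3K27me3 median of 0.54 lay at percentile 100 of random lists, which were not matched on H3K4me3. This median was below those of genes without an H3K4me3 call on the autosomes, 0.76 to 1.51. Of 22 genes of proteins secreted by the liver 1 had Ring1B, the fibrinogen gene Fgb at 2.92 (SD 0.79), while 3 had H3K27me3 and 2 had H3K4me3. The interval of this Ring1B share, 0.115% to 22.8%, includes the 7.98% of all genes, and the Ring1B median of 0.80 lay at percentile 87.8 of random lists. Alb, serum albumin, stood at 1.63 (SD 0.14) for Ring1B and 1.02 (SD 0.32) for H3K27me3.

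The list of thymic stroma genes, fixed before the data were examined, held epithelial, mesenchymal and vessel genes. Of 23 measured, 11 had H3K4me3, 7 had H3K27me3 and 7 had Ring1B. H3K4me3 lay at the keratin genes Krt5, at 6.13 (SD 0.93), Krt8, at 5.66 (SD 0.52), and Krt14, at 5.52 (SD 0.30), at Epcam, an epithelial adhesion molecule gene, at 6.05 (SD 0.34), and at Foxn1, the factor of thymic epithelium, at 5.14 (SD 0.24). The mesenchymal gene Pdgfra had H3K4me3 at 0.84 (SD 0.74) and Ring1B at 5.69 (SD 0.75), and the endothelial gene Pecam1 had 0.11 (SD 0.65) and 0.34 (SD 0.43). The H3K4me3 value of Prss16, a cortical epithelial protease gene, was 2.84 over the whole promoter and -0.06 within 1000 bases of the start site. On further lists added after the data were seen, H3K4me3 was called at 11 of 16 thymic epithelial regulators and products, 4 of 13 epidermal differentiation genes, 2 of 15 fibroblast genes, 1 of 13 endothelial genes and 1 of 14 neuronal genes. Ring1B was called at 8, 0, 3, 3 and 4 of these. The stroma list shares 8 measured genes with the thymic epithelial list, 5 with the fibroblast list and 3 with the endothelial list.

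**Figure D4:**
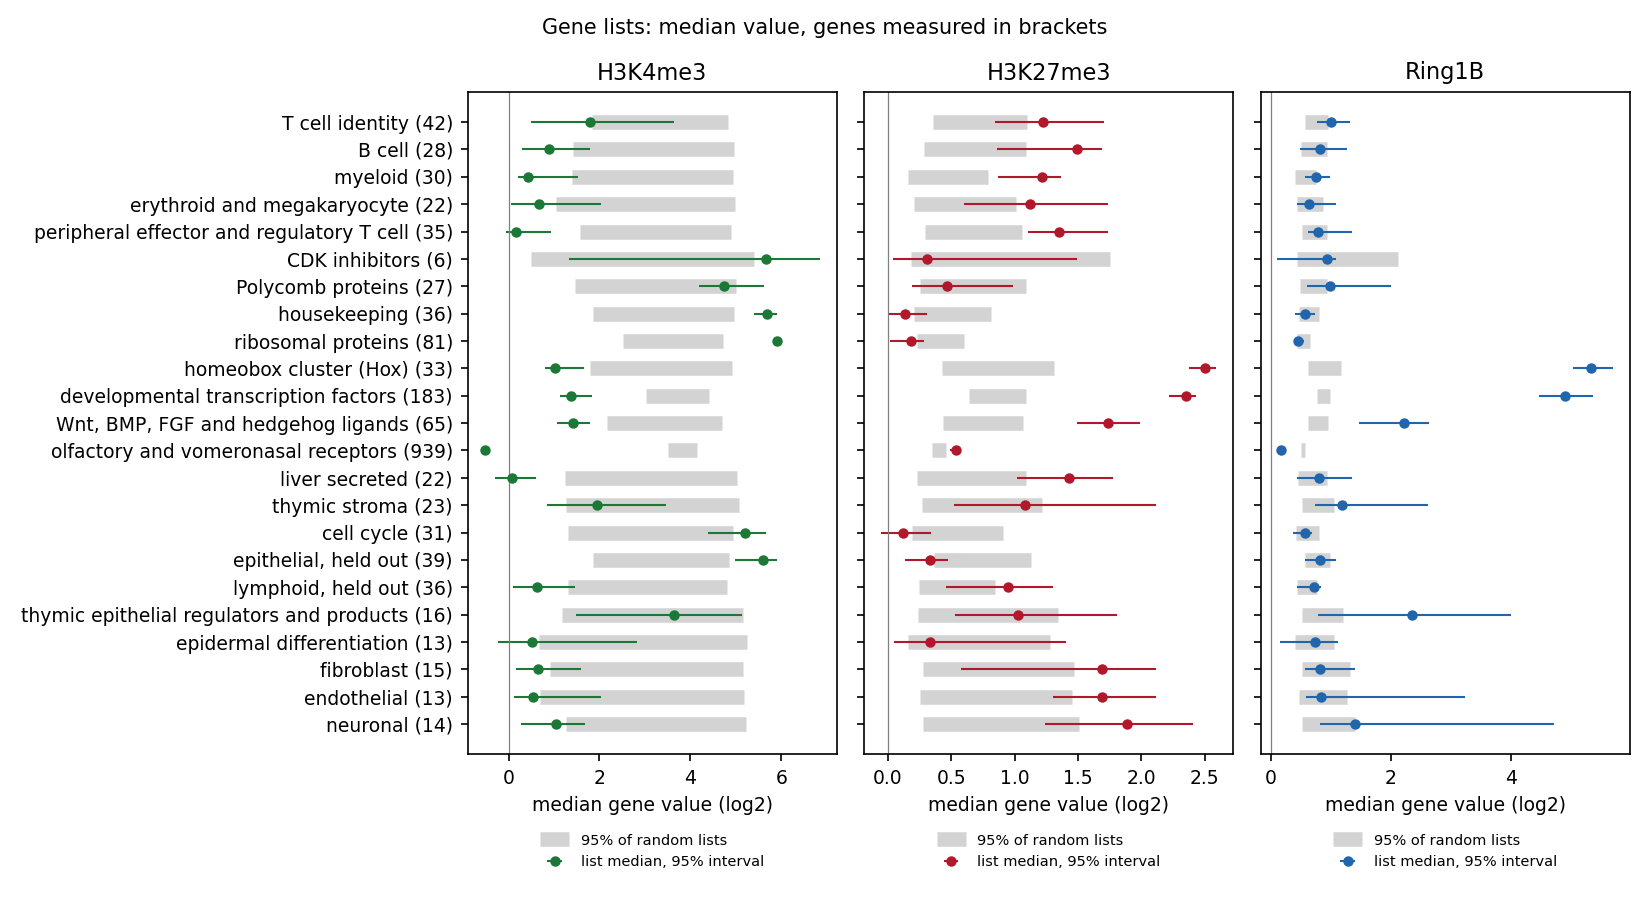
Median gene value (log2 ratio of ChIP over input, horizontal) of each gene list with its 95% order-statistic interval, by antibody; grey bars span 95% of random lists of that size, and brackets give the genes measured. The Hox list (33 genes) has a Ring1B median of 5.35, and the added epithelial list (39 genes) has an H3K4me3 median of 5.60 against 0.62 for the added lymphoid list (36 genes).

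By chromosome, H3K27me3 was raised along X. The median probe ratio was 0.90 on X, with 16720 probes, against -0.20 to 0.05 on the 19 autosomes. The X median of Ring1B, -0.08, lay within the autosomes' range of -0.09 to 0.08, and that of H3K4me3, -0.33, lay below their range of -0.19 to 0.20. Broad signal of this kind raised few single genes past the threshold: 25 of 552 X genes (4.53%, interval 2.95% to 6.61%) had an H3K27me3 call, within the autosomes' range of 4.25% to 9.83%. Pgk1, a glycolytic enzyme gene on X, had an H3K27me3 value of 1.43 (SD 0.35) with H3K4me3 at 5.73.

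**Figure D5:**
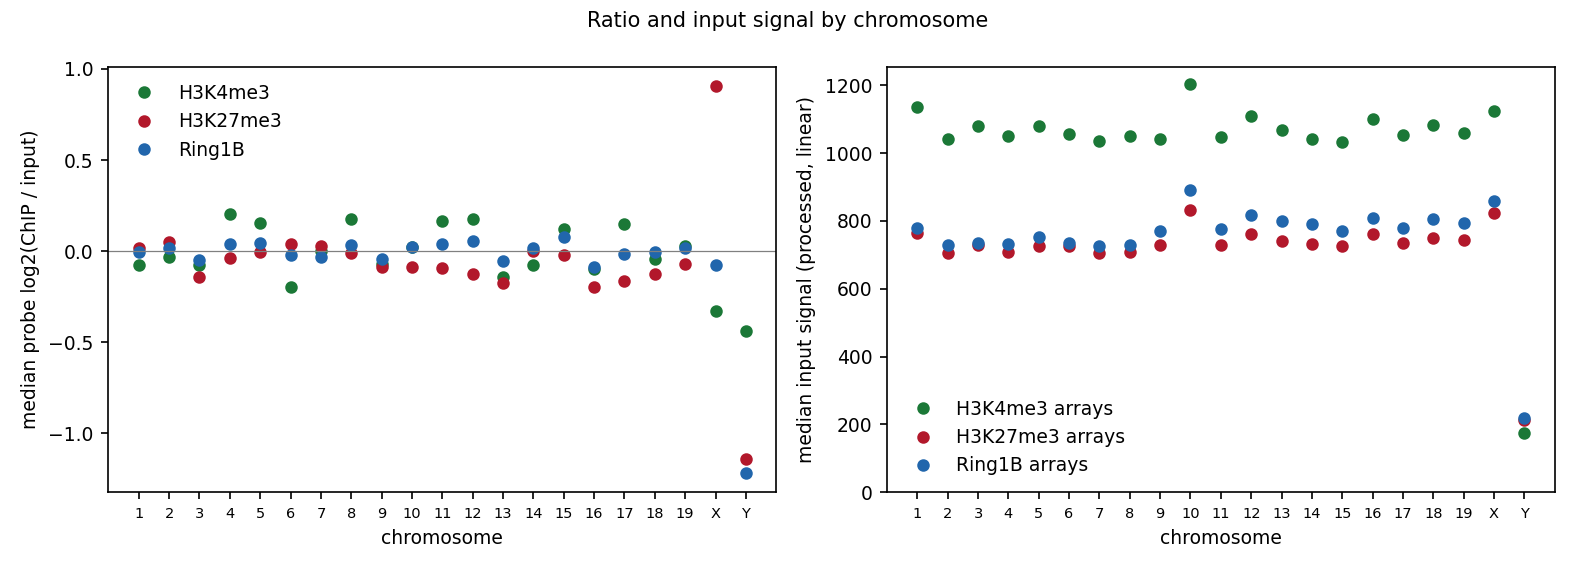
Median probe log2 ratio of ChIP over input (left) and median processed input signal on a linear scale (right) by chromosome, 1 point per antibody. X stands at 0.90 for H3K27me3, and the Y probes have input signals of 175, 214 and 220 on the H3K4me3, H3K27me3 and Ring1B arrays.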

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

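The loci without a RefSeq gene, and their values, were examined only after the promoter results had been seen. They comprise 417 tiled loci with 10894 probes and enter no comparison of the report. What drew attention is signal in data that no comparison used, above a limit of 0.719% set for a count of 0. The exact interval of a count of 0 reaches 0.881%. This is a low bar, and the intervals of the Ring1B and H3K27me3 shares below include the shares of genes. The highest windows of each antibody lay at transcripts of other collections (Ensembl or MGC), so these loci are not free of annotated transcripts. H3K4me3 passed its threshold at 119 of these loci (28.5%, interval 24.2% to 33.1%), against 61.3% of genes, and mirrored low windows occurred at 21. The highest window lay on chromosome 11 from 86401551 to 86402037, at 6.75 (SD 0.21). Ring1B passed its threshold at 29 loci (6.95%, interval 4.71% to 9.84%), against 7.98% of genes, with mirrored low windows at 2. The highest Ring1B window lay on chromosome 2 from 73576927 to 73577227, at 6.67 (SD 0.66). H3K27me3 passed its preset threshold at 0 loci and the added threshold of 2.03 at 31 (7.43%, interval 5.11% to 10.4%), against 6.91% of genes, with mirrored low windows at 8. Its highest window reached 2.72 (SD 0.26). No explanation was tested for these signals.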

How the results depend on the processing

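The count of low windows at genes without H3K4me3 only and the values within 1000 bases of the start site were chosen after seeing the data. No paired analysis was possible because numbers 1 and 2 name the arrays of a set, not replicates. The correction for GC content was not run, since probe sequences were not used here. Of 161 values of the main results under alternatives, 88 stayed within their limits, 72 moved and 1 turned sign by more than its limits. Of 5403 values of named genes, 3935 stayed, 1453 moved and 15 turned. Those that stayed include values that could not change, since the alternative leaves the probe ratios of a gene as they are. They were 546 under the deposited value table, 276 and 270 under array 1 and array 2 alone, and 525 with at least 10 probes. The deposited value table, which holds the same ratios, and a probe p-value under 0.01 moved none of the main results. No value could be given under the preset rule for genes with both marks, since there were 0. Surrogate values and raw input signals of 41.4 to 52.7 limit the low end of the ratios. Except where named, the cause was not tested.

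Normexp called H3K27me3 at 5300 and Ring1B at 5276 genes; Ring1B genes had H3K27me3 in 65.0% and H3K4me3 in 77.6%, and Ring1B was at 20.5% of genes with H3K4me3 alone and 5.02% with neither mark. Its rho was 0.658 for Ring1B with H3K27me3, 0.0966 for Ring1B with H3K4me3 and -0.224 for H3K27me3 with H3K4me3. Without centring, 1 gene had H3K27me3, so Ring1B was at 100% of genes with H3K27me3 alone, 25.3% of Ring1B genes had H3K4me3, and Ring1B was at 3.31% of genes with H3K4me3 alone. Centring on the mode left 1 H3K27me3 gene (100% with Ring1B), H3K4me3 at 68.8% of Ring1B genes, and Ring1B at 6.86% of genes with H3K4me3 alone and 6.51% with neither.

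The median of all probes called H3K4me3 at 3462 genes, H3K27me3 at 867 and Ring1B at 745. Of its Ring1B genes 56.5% had H3K27me3 and 4.97% had H3K4me3, Ring1B was at 1.07% of genes with H3K4me3 alone and 2.34% with neither, and rho was 0.0640 for Ring1B with H3K4me3 and -0.516 for H3K27me3 with H3K4me3. A median over the promoter lowers narrow peaks by construction, and H3K4me3 turned negative at Dmrt2 (-0.000231), Dsc3 (-0.11), Fgb (-0.39), Gnal (-0.20), Igf2bp1 (-0.0851), Ikzf1 (-0.29), Lmo2 (-0.16), Pde10a (-0.34), Rag2 (-0.56), Rpl30 (-0.22), Sp8 (-0.0312) and Tlr4 (-0.47). Windows of 5 probes called H3K27me3 at 448 genes, with H3K27me3 at 25.02% of Ring1B genes, Ring1B at 8.45% of genes with neither mark, and rho of 0.598, 0.0286 and -0.437 in the order above. Bright probes called H3K27me3 at 933 genes, with H3K27me3 at 39.9% and H3K4me3 at 60.8% of Ring1B genes, Ring1B at 7.52% of genes with H3K4me3 alone and 5.25% with neither, and rho of -0.00573 for Ring1B with H3K4me3, on the other side of 0 from the main value of 0.0132 but within the limits around 0. With at least 10 probes that rho turned to -0.0207, and that of H3K27me3 with H3K4me3 was -0.434.

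A threshold of 2-fold called H3K27me3 at 5267 and Ring1B at 4347 genes. Of these Ring1B genes 70.3% had H3K27me3 and 74.0% had H3K4me3, and Ring1B was at 14.1% of genes with H3K4me3 alone and 2.69% with neither. A mirrored share of 1% gave H3K4me3 at 35.0% of Ring1B genes, and Ring1B at 3.73% of genes with H3K4me3 alone and 10.11% with neither. The top 10% gave 1658 genes for H3K4me3 and 1658 for H3K27me3, H3K27me3 at 56.8% and H3K4me3 at 2.23% of Ring1B genes, and Ring1B at 2.06% and 5.15% of genes with H3K4me3 alone and neither. Low windows counted at genes without H3K4me3 gave 1146 H3K27me3 genes, 50.5% of Ring1B genes, and Ring1B at 4.32% and 4.11% of the same classes.

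Array 1 alone, with fewer genes, called H3K4me3 at 5061 and Ring1B at 676, and array 2 called H3K4me3 at 5097, H3K27me3 at 2 (100% with Ring1B) and Ring1B at 643. Within 1000 bases of the start site H3K27me3 was called at 799 genes, where no threshold met the rule and the top 5% was used. H3K27me3 was then at 37.6% and H3K4me3 at 45.6% of Ring1B genes, Ring1B was at 5.86% of genes with neither mark, and rho was 0.465, 0.0695 and -0.499. H3K4me3 turned negative at Fgb (-0.11), Foxp3 (-0.59) and Prss16 (-0.0601).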

Other observations

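The tests in this part were all chosen after the results they bear on had been seen. A small set of promoters combined Ring1B and H3K4me3 with low H3K27me3. Of the 431 genes with Ring1B and H3K4me3 and no H3K27me3 call, 28 had H3K27me3 below the median of all genes, 0.50. Of the 9554 genes with H3K4me3 alone and no Ring1B, 6569 lay below it, and their median was 0.25. Such values were thus common at H3K4me3 promoters without Ring1B and rare at those with it. Mirrored low windows, the error measure of the 1323 Ring1B calls, occurred at 61 genes, 41 of them without an H3K4me3 call, so errors among the 28 are not excluded. The 28 included Fgf9, a growth factor gene of lung and gonad, with Ring1B at 4.72 (SD 0.74), H3K4me3 at 6.08 and H3K27me3 at 0.36. Six2, a factor of kidney progenitors, had 3.37 (SD 0.75), 6.75 and 0.26. The tight junction gene Ocln had 3.83 (SD 0.50), 6.25 and 0.33, and Has2, a hyaluronan synthase gene, had 3.08 (SD 0.49), 5.08 and 0.24. The pair Dbr1 and Armc8, divergent neighbours that share a window, had Ring1B at 3.32 (SD 0.40).

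Of 16 thymic epithelial regulators and products, 5 had H3K4me3 together with Ring1B. Those named here were chosen after their values were seen, and 5 of the 16 are also on the list of developmental transcription factors, where Ring1B was frequent. Pax9, a factor of the pharyngeal pouches, had H3K4me3 at 5.36 (SD 0.80) and Ring1B at 4.01 (SD 0.60). Eya1, a transcriptional coactivator of the same region, had 4.11 (SD 0.76) and 5.51 (SD 0.51), and Tbx1, the factor of the 22q11 deletion region, had 5.09 (SD 0.44) and 3.04 (SD 0.41). Pax1 had H3K4me3 at 6.33 (SD 0.17) and Ring1B just under its threshold, at 2.23 (SD 0.12). Foxn1, Krt5 and Krt14 had no Ring1B call.

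The first pattern weighed is that 23 of 42 T cell identity genes, among them Cd3d, Cd3e and Cd3g, lacked an H3K4me3 call. Most genes of the added epithelial list had one. Missing probes are argued against, since 100% of the 23 T cell identity genes without H3K4me3 had a probe within 500 bases of the start site. Exchanged H3K4me3 and H3K27me3 arrays are argued against by housekeeping genes, 36 of 36 of which were called on the arrays labelled H3K4me3, and a small share of epithelial cells among T cells by the added lymphoid list, where 25% had H3K4me3. Going the other way, 19 of 42 T cell identity genes had H3K4me3, among them Lck at 4.74 and the pre-T cell receptor gene Ptcra at 4.18. A share of T cell chromatin thus stays open. The 19 include Rag2, whose window lay away from its start site. How many of the 19 genes other cells also express, and how many of the epithelial genes T cells also express, was not assessed. A candidate explanation, as a hypothesis, is that the chromatin came mainly from epithelial cells: 92.3% of the epithelial list had H3K4me3, among them Itgb4 and Klf5, against 2 of 15 fibroblast, 1 of 13 endothelial and 1 of 14 neuronal genes, while no sort is named in the labels, and 11 of 16 thymic epithelial against 4 of 13 epidermal genes leave the kind of epithelium open.

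The second pattern is raised H3K27me3 along X. The X median of Ring1B, -0.0757, lay within the autosomes' range, while that of H3K4me3, -0.33, lay below it. These medians cannot decide on an unequal amount of X DNA, since each array had its own input channel. The X input signal on the H3K27me3 arrays, given below, lay within the autosomes' range. Fewer H3K4me3 promoters on X do not account for it, since X genes with an H3K4me3 call had a median H3K27me3 of 1.30, above the autosomes' range of 0.12 to 0.35, while X genes without one had 1.54, close to the highest autosome at 1.51. A candidate explanation is the inactive X of female cells, as a hypothesis: the 204 Y probes had a median input signal of 214 on the H3K27me3 arrays, against 707 to 832 on autosomes and 822 on X. The labels do not give the sex of the animals, and Y probes may also read low because of their sequence, which was not tested.

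The third pattern is Ring1B at H3K4me3 promoters without an H3K27me3 call. General enrichment of H3K4me3 promoters in the Ring1B ChIP as the cause of the calls is argued against by the highest of 10 bins by H3K4me3. There 1.21% of genes had Ring1B, against 7.98% of all genes and 4.32% of genes with H3K4me3 alone. The 7.98% includes genes with H3K27me3 calls, and the bins were not split by H3K27me3, so that mark was not held constant. A weaker enrichment that adds to the Ring1B values stays open, since Ring1B and H3K4me3 had a rho of 0.27 at the 8291 genes with H3K27me3 below its median. Another candidate explanation, as a hypothesis, is H3K27me3 below the threshold: the 431 genes had a median H3K27me3 of 1.47 (interval 1.39 to 1.53) against 0.25 (interval 0.24 to 0.26) for the other 9554, and 343 exceeded 2-fold. The 28 genes with low H3K27me3 stay open, as do mixtures of cells or alleles, which were not tested.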
